A study of Homo sapiens with 6 samples.

How the data were processed

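Gene expression was measured on Affymetrix Human Gene 2.0 ST arrays, a whole-transcript oligonucleotide array, in 3 established human multiple myeloma cell lines, RPMI8226, KMS11 and U266. Per the labels' protocols, each line received either a miR-10a mimic or a scrambled control at 100 nM with the HiPerFect reagent, cells were collected after 48 h, and biotin-labelled target was made from total RNA. There was 1 array for each line and treatment, 6 arrays in all. The groups were taken from the labels: 3 mimic arrays and 3 scrambled-control arrays. IM-9, another line named in the design text, was not analysed here.

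The authors deposited 1 table of log2 expression values for 53617 probe sets. Affymetrix Expression Console 1.3.0 is named in the submitters' processing notes. The background correction, the normalization, the summarization and the genome build are not given in the sources used here. Medians over all probe sets lay between 3.61 and 3.66 log2 units in the 6 arrays, and whether arrays were centred against one another before deposit stays unknown. No 2 arrays held identical values. The table gives no detection calls and no spot-level signal, so whether a probe set stood above background is unknown, and low log2 values were read as uncertain. A summary of this kind can compress changes of weakly expressed genes toward 0. The number of arrays limits the precision of every value.

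Probe sets were named through the platform annotation supplied with the series. It gave 1 gene symbol for 16098 probe sets and several symbols for 0, and 37519 probe sets remained unnamed here. All 16098 gene identifiers matched the reference gene table (GRCh38.p14), and 0 symbols needed an update. These probe sets stood for 14884 genes. No genome coordinates are printed, because the build behind the array summaries is not stated. For the 779 genes with several probe sets, the one with the highest mean over the 6 arrays was used. Genes with a mean at or above the median of all named genes (4.70 log2 units) were tested, which left 7442 genes, 6797 of them protein-coding and 199 microRNA genes.

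The mimic was compared with the scrambled control in limma 3.58.1 under R 4.3.3 (lmFit and eBayes, without trend), with the cell line as a block. P-values were two-sided and adjusted with the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. The pairing comes from the cell line label. Deviations of the 2 arrays of a line from their treatment means correlated at 0.97 in RPMI8226, 0.967 in KMS11 and 0.97 in U266, across genes. The fit left 2 residual degrees of freedom and a prior of 3.82 degrees of freedom. The labels name no separate cultures within a line, so the spread is that between lines. A full interaction of mimic and line leaves no residual degrees of freedom, and the plan held no test of it. After the data were seen, the mimic effect of each line in turn was tested against that of the other 2, with a term for that line's own effect beside the shared effect and the cell line. That fit leaves 1 residual degree of freedom, the difference between the other 2 lines' changes, and its list tests were adjusted over the 54 combinations of list and line. Other per-line changes are values without a test. Differences between lines were tested in the same fit with an F test and with pairwise contrasts, each line being represented by 2 arrays that differed in treatment.

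In all, 22 gene lists were fixed before the data were examined: miR-10 family targets, 2 receptors recalled from the study, HOX genes, EPH receptors and ephrins, the IGF axis, the TGF-beta pathway, the NF-kB pathway, cell cycle and DNA replication, p53 targets, apoptosis regulators, the unfolded protein response, plasma cell genes, B cell genes, stromal cell genes, T cell and myeloid genes, interferon-stimulated genes, hypoxia genes, cholesterol synthesis, myeloma oncogenes, microRNA machinery, histone genes and ribosomal protein genes. The miR-10 family target list was written from memory and not from a prediction database. EPHA8 and IGF1R were listed because a report on these cells was recalled to name them, so their values are not independent evidence where the study chose them on these arrays. The lists held 538 symbols, of which 341 were named on the array and 239 were tested. Older symbols were matched through the reference table's synonyms. The 18 lists with at least 3 tested members were tested with camera (preset inter-gene correlation of 0.01, two-sided, Benjamini-Hochberg over the 18 lists), with an estimated correlation and fry as alternatives. With an estimated correlation, camera takes its p from the residual degrees of freedom alone, and it called a list in 0% of 50 simulations with a shift of 0.5 log2 units in all 3 lines and in 0% with a shift of 1 log2 unit in U266, so its p-values are not printed. Fry called the miR-10 family target list in 10% of 50 simulations with a shift of 0.1 in all lines, against 96% for the preset. In a run added after the data were seen, each list's estimated correlation, not below 0, was given to camera as a fixed value. That run called the list in 92% of the same simulations. The estimated correlation comes from 2 residual degrees of freedom, or 1 without a line or for 1 line against the other 2. None of the histone genes was named by the annotation. Per line, a list's median change was set against 10000 random lists matched on mean expression in 10 bins, as a description of those arrays. Random lists hold unrelated genes and do not carry the co-regulation of a pathway.

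Genes were named by a rule fixed before the data were examined: the 12 largest increases and 12 largest decreases past the threshold with the same direction in all 3 lines. A direction with fewer such genes was filled with the genes having the largest smallest-change over the 3 lines. Members of each list past the threshold were named, otherwise the 2 with the largest mean change, together with EPHA8, IGF1R, MIR10A and genes next to it. Genes named for a line were the 6 protein-coding genes highest and the 6 lowest against both other lines, and the 4 widest changes each way within a line, both rules being set after the files were opened. Y-linked genes and XIST were left out of naming.

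The scripts were tested on simulated data with the means and line effects of the 7442 genes and variances drawn from the fitted prior. In each of 20 simulations, 200 genes were given changes of mixed size, each change being the same in all lines. The mimic comparison recovered 1.7% of genes changed 1.2-fold, 73.6% of those changed 1.5-fold, 97.5% of those changed 2-fold and 99.2% of those changed 3-fold. Of its calls, 4.97% were false. In 100 simulations per size, the 25 tested miR-10 family targets were called lower in 19% when all fell by 0.05 log2 units and in 96% when all fell by 0.1. With the spread drawn from each line's own fit, the test of 1 line against the other 2 recovered 0%, 30.8% and 69.1% of genes changed 2-fold in RPMI8226, KMS11 and U266 alone, and 91.7%, 97.1% and 98.9% of those changed 3-fold. With the spread of the fit of all lines, it recovered 5.5% of genes changed 2-fold in U266, so this recovery depends on the assumed spread. For U266, with the spread of the fit of all lines and adjustment over the 18 lists, it called the 18 interferon-stimulated genes in 0% of 100 simulations without a shift, in 9% when they fell by 0.1 log2 units in U266 and in 77% when they fell by 0.2, with genes simulated as independent.

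Alternatives planned before the data were examined were no filter, an upper-quarter filter, the mean of a gene's probe sets, quantile normalization, array medians centred, leaving out each line, the fit without the cell line block, eBayes with trend and robust, a plain paired test per gene, other fold thresholds and other set tests. Tests on all probe sets, on protein-coding genes only and of the line differences without each array, the interferon-stimulated genes of U266 under other scalings, the given correlation, and the test of 1 line against the other 2 were added after the data were seen. The planned test of genes with miR-10a seed sites was not run, because no 3' UTR sequences were used here. Figures were drawn with matplotlib 3.10.9.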

Results

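The data comprised 6 whole-transcript expression arrays from 3 multiple myeloma lines, established lines of malignant plasma cells. RPMI8226, KMS11 and U266 each contributed 1 array after transfection with miR-10a mimic and 1 after transfection with scrambled control. The question was which transcripts change when miR-10a, a microRNA encoded in the HOXB cluster, is supplied in excess. Over the 7442 tested genes, the 2 arrays of a line correlated at 0.992 to 0.993, and arrays of different lines at 0.715 to 0.779. The line, not the treatment, therefore separated the arrays.

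The line labels were first set against genes driven by recurrent myeloma translocations. MAF, a transcription factor gene activated by a translocation, stood at 10.57 and 10.56 log2 units in the control and mimic arrays of RPMI8226, at 8.96 and 8.91 in KMS11, and at 4.57 and 4.96 in U266. FGFR3, a receptor tyrosine kinase gene, reached 8.62 and 8.69 in KMS11 but 3.93 and 3.95 in RPMI8226 and 3.56 and 3.78 in U266. NSD2, a histone methyltransferase gene deregulated together with FGFR3, was also highest in KMS11, at 7.87 and 7.77. CCND1, encoding cyclin D1, was highest in U266, at 9.98 and 10.0. MYC stood at 10.83 and 10.75 in RPMI8226 and at 4.92 and 4.43 in U266. The widest gap between the 2 arrays of a line in these genes was 0.49 log2 units, for MYC in U266, so both arrays of each line carried the same pattern.

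**Figure D1:**
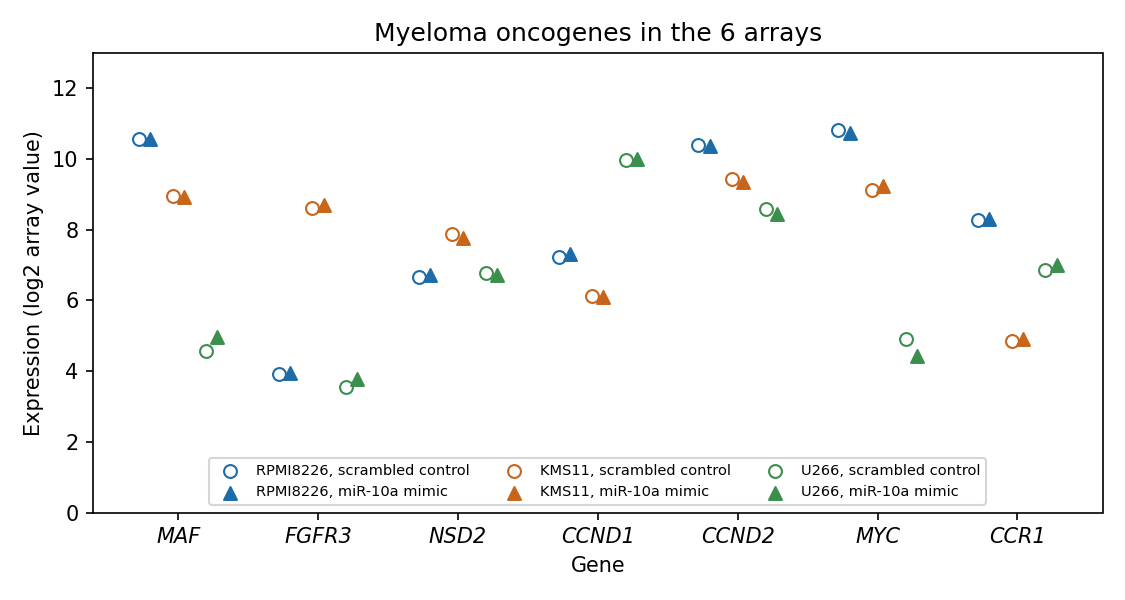
Expression (log2 array value) of 7 myeloma oncogenes in each of the 6 arrays, with colour for the cell line, open circles for scrambled control and filled triangles for miR-10a mimic. The 2 arrays of a line lie close together, with MAF at 10.57 and 10.56 in RPMI8226 and FGFR3 at 8.62 and 8.69 in KMS11.

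Uptake of the mimic was not measured here, and whether an array of this kind detects a transfected mimic was not tested. MIR10A was not among the named probe sets. Its closest relative with a named probe set, MIR10B, lay near the bottom of the scale, at 2.11 ± 0.078 log2 units in the controls and 2.01 ± 0.10 with mimic (SD, n = 3). HOXB2 to HOXB6, the cluster genes nearest to MIR10A, were below the expression filter. The log2 change of HOXB3 was 0.12 ± 0.11 at a mean level of 4.50, that of HOXB4 -0.19 ± 0.21 at 3.35, and that of HOXB5 -0.02 ± 0.07 at 2.47 (SD of 3 lines). HOXB2 averaged 3.18 and was lower with mimic in all 3 lines, by -0.40 in RPMI8226, -0.36 in KMS11 and -0.13 in U266, with limma's adjusted p = 0.949 when no filter was applied.

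No gene was called as changed by the miR-10a mimic across the 3 lines. Of 7442 genes, 0 passed an adjusted p of 0.05 in limma with the cell line as a block, and the smallest adjusted p was 0.889. A plain paired test per gene called 0 as well, with 402 genes at an unadjusted p under 0.05, and limma without the block called 0, with 2. With the block, 403 genes lay at an unadjusted p under 0.05, 183 higher and 220 lower with mimic, where chance alone gives 372. The same direction in all 3 lines was seen for 1972 genes, or 26.5%, where chance gives 25%. A change of at least 1.5-fold in the same direction in every line was seen for 0 genes, and turning the sign of a single line gave 0, 0 and 1. At least 1.2-fold in every line was reached by 16 genes, 4 higher and 12 lower, against 18, 10 and 17 with the sign of RPMI8226, KMS11 or U266 turned.

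The 95% confidence interval of a gene's mean change, not corrected for the number of genes, excluded 1.5-fold in either direction for 7265 genes (97.6%) and 2-fold for 7438 (99.9%). The median half-width of the interval was 0.19 log2 units. These bounds hold on the scale of the array values, which can compress changes of weakly expressed genes toward 0. Changes were simulated in 200 of the 7442 genes, each of the same size in all 3 lines. Of these, 73.6% of those of 1.5-fold and 97.5% of those of 2-fold were recovered, but 1.7% of those of 1.2-fold. Small shared changes were therefore not detectable with 3 pairs of arrays. Recovery of fewer changed genes, or of changes unequal between lines, was not simulated for this comparison.

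Among the genes named by rule as higher with mimic, none past the threshold, the widest mean change was that of SLC66A1, a lysosomal amino acid transporter gene, at 0.52 ± 0.26 (log2 change, SD of 3 lines), or 1.44-fold. MIR3691 followed at 0.46 ± 0.18, then LINC01144 at 0.43 ± 0.15, PRNP, the prion protein gene, at 0.43 ± 0.21, and CALML3, a calmodulin-like gene, at 0.43 ± 0.08. MRI1, an enzyme of the methionine salvage pathway, had the most even change, 0.40 in RPMI8226, 0.39 in KMS11 and 0.39 in U266. The zinc finger genes ZNF383 and ZNF584 gave 0.37 ± 0.11 and 0.28 ± 0.05. TRMT10C, a subunit of mitochondrial RNase P, gave 0.36 ± 0.14, RPUSD2, a pseudouridine synthase gene, 0.36 ± 0.17, MIR191 0.31 ± 0.13 and DHRS7, a short-chain dehydrogenase gene, 0.30 ± 0.04. Each had limma's adjusted p = 0.889.

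Of the 12 genes named as lower with mimic, none past the threshold, GSTT1, a glutathione transferase gene, had the widest mean change, -0.63 ± 0.29, or 1.55-fold lower. MIR3135B gave -0.58 ± 0.28, and OBP2A gave -0.52 ± 0.42, of which RPMI8226 alone gave -1.01. OBP2A has a near-identical copy, so its probe set is uncertain. GARS1-DT, a divergent transcript of the glycyl-tRNA synthetase gene, gave -0.49 ± 0.16. MIR644A, MIR4682, MIR421 and MIR646 gave -0.44, -0.41, -0.36 and -0.36. ANO10, an anoctamin gene, gave -0.36 ± 0.03, MEIS1, a HOX cofactor gene, -0.35 ± 0.05, and PF4, the platelet factor 4 chemokine gene, -0.34 ± 0.06. RORA, a nuclear receptor gene on the miR-10 family target list, gave -0.29 ± 0.04, with -0.27 in RPMI8226, -0.34 in KMS11 and -0.27 in U266. Each again had limma's adjusted p = 0.889.

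**Figure D2:**
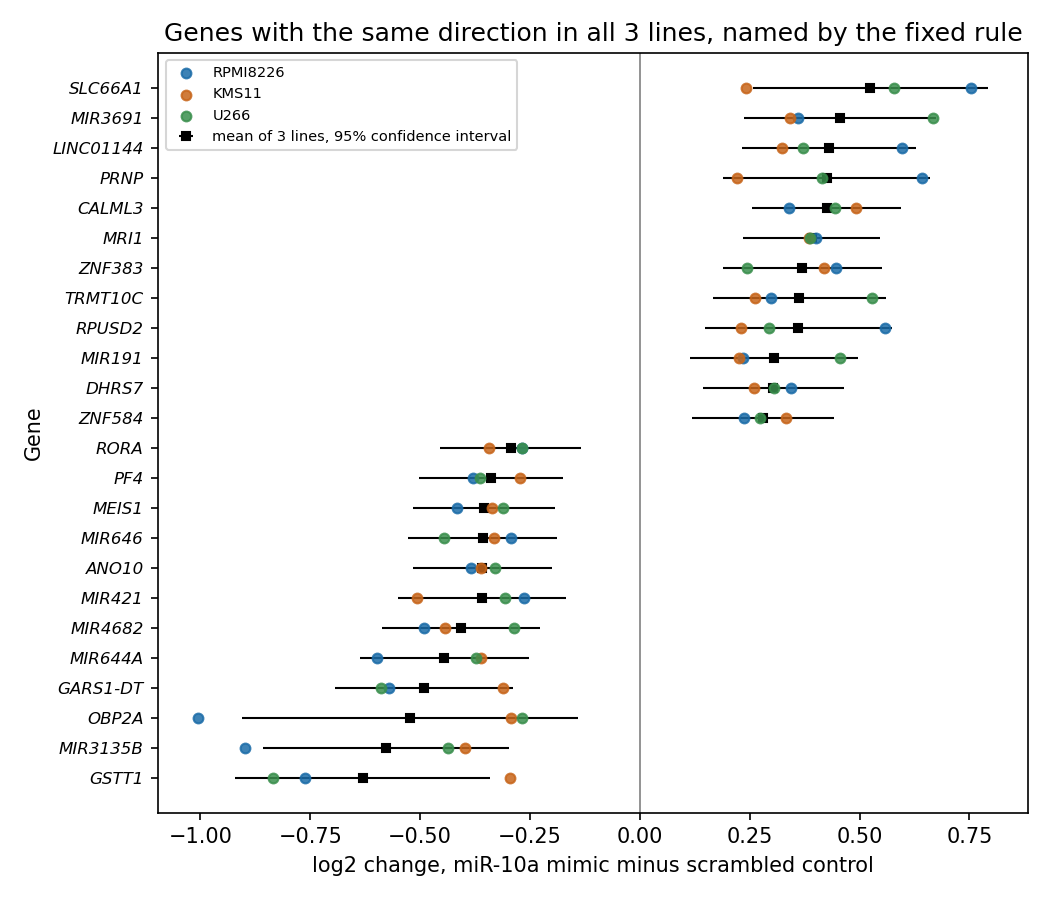
Change with miR-10a mimic (log2, horizontal axis) of the 24 genes named by rule (vertical axis), with coloured points for the 3 lines and black squares with bars for the mean and its 95% confidence interval, not corrected for the 7442 genes tested. RORA lies at -0.27, -0.34 and -0.27 in the 3 lines, and none of the 24 passed the adjusted threshold.

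Genes listed as miR-10 family targets did not pass the test as a list. Of 25 tested members, 0 passed the threshold in either direction, and by sign alone 18 were lower and 7 higher. The median change of the list was -0.05 log2 units (limma's camera, adjusted p = 0.088 over the 18 lists, unadjusted 0.0097). With the list's estimated correlation given to camera as a value, the adjusted p was 0.0792, and fry gave an adjusted p of 0.139. The camera adjusted p was 0.243 without RPMI8226, 0.25 without KMS11 and 0.23 without U266. It was 0.418 with no filter, 0.522 without the block and 0.0527 with a variance trend in camera, so the list passed in none of these. The list's median was -0.02 in RPMI8226, -0.05 in KMS11 and -0.04 in U266, with 15, 17 and 17 members lower. Its members with the widest mean changes were RORA and KLF4, a pluripotency-associated transcription factor gene, which gave 0.27 ± 0.20. No member passed when p was adjusted over the list alone (smallest 0.109).

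IGF1R, the receptor for insulin-like growth factor 1, averaged 7.03 log2 units in the controls and 6.96 with mimic (probe set 16805495). Its change was -0.08 ± 0.08 (SD of 3 lines), with a 95% confidence interval from -0.28 to 0.13 in the fit of all named genes and an adjusted p of 0.968 there. Without RPMI8226 it was -0.03. EPHA8, an ephrin receptor gene, averaged 3.02, below the filter (probe set 16660555). It was higher with mimic by 0.28 in RPMI8226, 0.10 in KMS11 and 0.74 in U266, a mean of 0.37 ± 0.33, with limma's adjusted p = 0.949 without the filter. Both receptors were listed because a study of these cells was recalled to name them. Neither is independent evidence where that study chose them on these arrays, which is not known here. The EPH and ephrin list had 2 tested members, too few for a set test. EFNA4, an ephrin ligand gene, gave 0.42 ± 0.34, with 0.77 in RPMI8226, 0.10 in KMS11 and 0.38 in U266. EFNA3 gave -0.11 ± 0.09. Adjusted over the list alone, which does not correct for the number of lists, EFNA4 passed (0.0379), against 0.889 over all genes. The IGF axis had 7 tested members, 0 past the threshold, 6 of them higher, with a median of 0.08, or 0.02 without KMS11 (camera adjusted p = 0.334). Its widest members were IGFBP4 and IGFBP3, binding protein genes, at 0.22 ± 0.44 and 0.20 ± 0.32, with IGFBP4 at -0.01 without U266. Without RPMI8226, camera called the IGF axis higher (adjusted p = 0.0292), but not with the list's estimated correlation given as a value (adjusted p = 0.585). The HOX list had 3 tested members, with HOXB9 at 0.12 ± 0.33 (-0.05 without U266) and HOXB7 at 0.09 ± 0.07 (list median 0.09, camera adjusted p = 0.45). Over the 27 HOX genes named on the array, with no filter, the list's median was 0.0050 (camera adjusted p = 0.996).

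In the NF-kB pathway list, TRAF1, a TNF receptor adaptor gene, was lower in every line (-0.36 ± 0.11) and RELB, a subunit of the noncanonical NF-kB dimer, was higher in every line (0.28 ± 0.07). Both passed when p was adjusted over the list alone (2 of 14 members, smallest 0.0422) and neither passed over all genes (0.889 each). Adjustment over a list alone was made for each list and does not correct for the number of lists. The list's median was 0.0037, or -0.0047 with array medians centred and -0.02 without RPMI8226, its mean was -0.02 and its camera direction downward (adjusted p = 0.853). In the TGF-beta list, 8 tested members had a median of -0.03, or -0.0040 without RPMI8226 (adjusted p = 0.847), with BAMBI, a TGF-beta pseudoreceptor gene, at 0.25 ± 0.07 and SKIL at -0.12 ± 0.11.

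Genes of growth control and stress did not pass the test either. Of 11 tested p53 targets, 10 were higher with mimic, with a median of 0.05 (limma's camera, adjusted p = 0.088, unadjusted 0.0096). AEN, a p53-induced nuclease gene, gave 0.19 ± 0.16 and BBC3, encoding the pro-apoptotic protein PUMA, gave 0.14 ± 0.06. The cell cycle list had 37 members, 26 higher and 11 lower, and a median of 0.03 (adjusted p = 0.216). That median came mainly from RPMI8226, where it was 0.08, against -0.0017 in KMS11 and -0.02 in U266, and was 0.0066 without RPMI8226. KIF20A gave 0.14 ± 0.43, of which RPMI8226 gave 0.64, and -0.11 without that line, and E2F1 gave 0.14 ± 0.16. Apoptosis regulators (19 genes, median 0.04, or -0.0070 in the upper 25% of genes by expression, adjusted p = 0.334) included BIK at 0.18 ± 0.14 and XIAP at 0.18 ± 0.24. Genes of the unfolded protein response (19 genes, median 0.03, adjusted p = 0.374) included DDIT3, encoding CHOP, at -0.20 ± 0.10 and MANF at 0.16 ± 0.07. Ribosomal protein genes (20 genes, 16 higher, median 0.04, limma's camera, adjusted p = 0.163, unadjusted 0.036) included RPS19 at 0.16 ± 0.08 and RPL35 at 0.14 ± 0.12.

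Hypoxia genes (15 genes, median 0.0059, or -0.0026 with array medians centred, -0.00066 without KMS11 and 0.02 after quantile normalization, adjusted p = 0.906) included ADM, the adrenomedullin gene, at -0.18 ± 0.12 and MXI1 at 0.15 ± 0.05. Cholesterol synthesis genes (16 genes, median 0.02, or -0.01 without KMS11 and 0.04 in the upper 25% of genes, adjusted p = 0.842) included IDI1 at -0.12 ± 0.09 and HSD17B7 at -0.11 ± 0.22 (-0.01 without U266). MicroRNA machinery genes (8 genes, median -0.0051, or 0.02 after quantile normalization, -0.05 without RPMI8226 and 0.04 without KMS11, adjusted p = 0.882) included TNRC6A, a partner of Argonaute, at -0.13 ± 0.11 and DDX6 at 0.09 ± 0.10. Myeloma oncogenes (7 genes, median 0.03, or 0.0019 in the upper 25% of genes by expression and -0.0066 without RPMI8226, adjusted p = 0.843) included MYC at -0.15 ± 0.31 and MAF at 0.11 ± 0.25, which were 0.02 and -0.03 without U266.

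Plasma cell genes (11 genes, median 0.00033, or -0.0027 after quantile normalization and -0.0081 with array medians centred, from -0.02 to 0.02 without a line, mean -0.02, camera direction downward, adjusted p = 0.843) included CD38 at -0.12 ± 0.17 (-0.03 without U266) and SUB1 at -0.08 ± 0.15 (-0.02 without KMS11). Markers of other cell types also did not pass. B cell genes (3 genes, median -0.05, but 0.12 without RPMI8226, -0.26 without KMS11 and 0.02 without U266, adjusted p = 0.697) included BLK, a B cell kinase gene, at -0.22 ± 0.07 and SPIB at 0.10 ± 0.14 (0.02 without U266). T cell and myeloid genes (3 genes, median 0.07, or -0.0010 with no filter, adjusted p = 0.565) included CD8A at 0.19 ± 0.45 (-0.07 without RPMI8226) and CD5 at 0.07 ± 0.02. The 2 tested stromal genes, FN1 (fibronectin) and VIM (vimentin), gave 0.05 ± 0.07 and 0.02 ± 0.05, with VIM at 0.08 as the mean of its probe sets and -0.0049 without RPMI8226.

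Interferon-stimulated genes had lower values with mimic in the 1 pair of U266 arrays. In that pair 16 of 18 tested members were lower, with a median change of -0.24 log2 units, and 0 of 10000 random lists matched on expression had a median as low. XAF1, an interferon-induced pro-apoptotic gene, gave -0.96, USP18, a negative regulator of interferon signalling, gave -0.72, ISG15, a ubiquitin-like modifier gene, gave -0.54 and IFIT5 gave -0.47, with USP18 and IFIT5 singled out after their values were seen. The median of the list was 0.04 in RPMI8226 and 0.02 in KMS11, where 5 and 8 members were lower. Across the 3 lines, the list had 0 members past the threshold, XAF1 gave -0.39 ± 0.50 and -0.10 without U266, ISG15 gave -0.27 ± 0.24, and the list's median was -0.10 (limma's camera, adjusted p = 0.163, unadjusted 0.034). With a line left out, the list's camera adjusted p was 0.0292 without RPMI8226, 0.0383 without KMS11 and 0.927 without U266. The first 2 calls were lost with the list's estimated correlation given as a value (adjusted p = 0.721 and 0.69), though the residuals behind those estimates hold the change of U266 itself. Tested against the other 2 lines, the list was called lower in U266 with the preset correlation (camera adjusted p = 4.37e-05) but not with the correlation of 0.15 estimated in that fit given as a value (adjusted p = 0.249), an estimate resting on 1 residual degree of freedom.

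**Figure D3:**
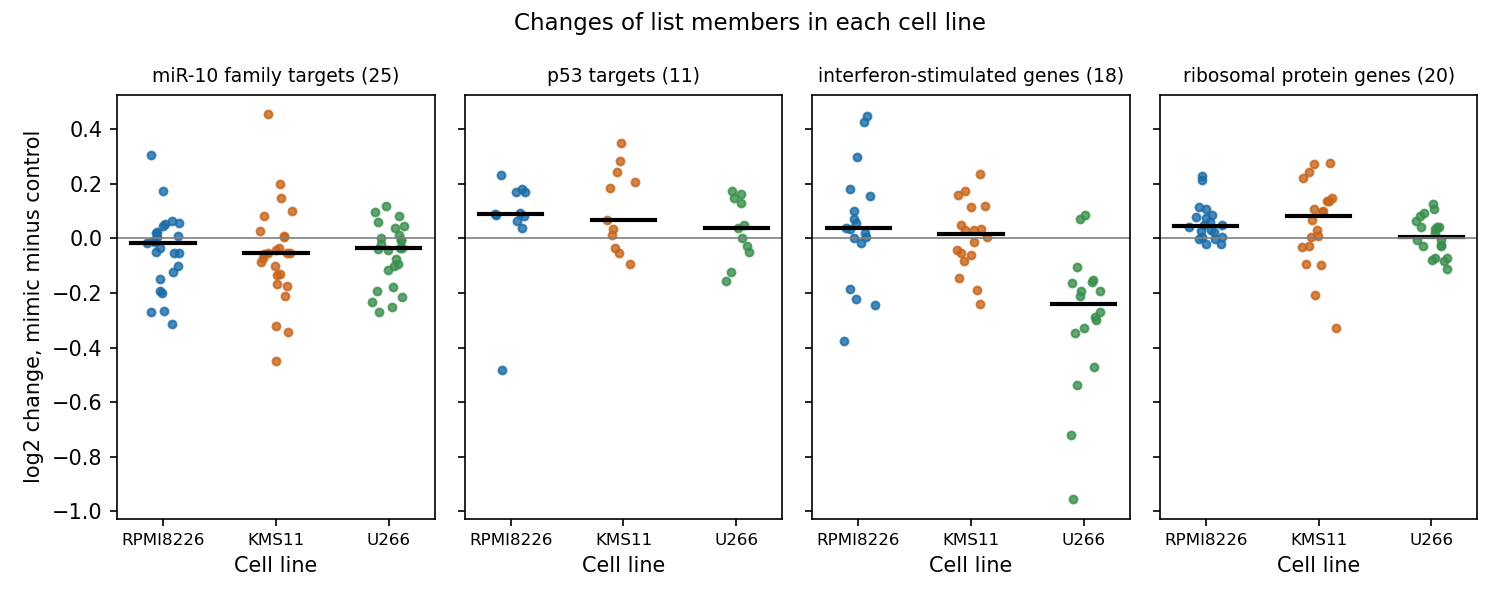
Change with miR-10a mimic (log2, vertical axis) of each tested member of 4 gene lists in each cell line (horizontal axis), with points for genes and black bars for list medians. Interferon-stimulated genes have a median of -0.24 in U266, 0.04 in RPMI8226 and 0.02 in KMS11, and the medians of the other lists lie between -0.05 and 0.09.

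The changes of the 3 lines correlated little with one another across genes. Pearson's r across the 7442 genes was 0.02 between RPMI8226 and KMS11 (Spearman's rho 0.01), -0.05 between RPMI8226 and U266 (rho -0.03), and 0.06 between KMS11 and U266 (rho 0.10). Genes are not independent replicates, so no p is given for these 3 correlations. The SD of the change over all genes was 0.19 in RPMI8226, 0.18 in KMS11 and 0.19 in U266. In RPMI8226, 41 genes were at least 1.5-fold higher with mimic and 37 lower, in KMS11 32 and 33, and in U266 41 and 39. These counts have no replicate check.

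The widest changes of protein-coding genes within single lines mostly had no counterpart of that size in another line. GSTT1 was an exception, at -0.76 in RPMI8226 and -0.84 in U266, as was MSTO1, at 0.81 in RPMI8226 and 0.77 in KMS11. In RPMI8226, LAPTM4B, a lysosomal membrane protein gene, was 1.33 log2 units higher with mimic, against 0.10 in KMS11 and -0.01 in U266, but its mean level there was 3.09, at the low end of the arrays, and PCBD1 was lower by -0.82. In KMS11, DOK6, an adaptor gene, was 1.04 higher and the zinc finger gene ZNF844 was lower by -1.17, against -0.51 and -0.13 in U266. In U266, IFITM2, an interferon-induced antiviral gene, was lower by -1.01, against 0.54 in RPMI8226 and -0.41 in KMS11, and SMOX, the spermine oxidase gene, was 0.90 higher. The test of 1 line's mimic effect against that of the other 2, which rests on 1 residual degree of freedom, called 0 of 7442 genes for each line (limma, smallest adjusted p = 0.748 for RPMI8226, 1.00 for KMS11 and 0.254 for U266). Genes were also simulated as changed 2-fold in 1 line alone. With the spread of that line's own fit, the test recovered 0% for RPMI8226, 30.8% for KMS11 and 69.1% for U266. With the spread of the fit of all lines, it recovered 5.5% for U266, so recovery depends on the assumed spread. Differences of that size can therefore be missed in each line.

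Differences between the lines had a median size of 0.43 to 0.48 log2 units over all tested genes. Of 7442 genes, 6135 (82.4%) differed between lines in limma's F test at an adjusted p under 0.05, with 2 arrays per line. KMS11 was higher than RPMI8226 for 2653 genes and lower for 2185. U266 was higher than RPMI8226 for 2609 and lower for 2408, and higher than KMS11 for 2218 and lower for 2530. Between 1366 and 1652 genes differed at least 2-fold in each contrast. The 2 arrays of a line differed in treatment and their separate culture is not stated. These p-values set line differences against the spread of the mimic-minus-control change over the lines, not against separate cultures of a line.

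RPMI8226 stood furthest above both other lines for CXCL10 and FN1. CXCL10, an interferon-induced chemokine gene, averaged 10.6 log2 units there, against 2.81 in KMS11 and 2.32 in U266, and FN1 averaged 12.8, against 6.01 and 4.74. The difference of CXCL10 between KMS11 and RPMI8226 was -7.80 (SE 0.11, limma's adjusted p = 9.7e-07). LTF (lactoferrin), PLEK, LY86 and GPX7 were also at least 5.25 log2 units above both other lines. Among the genes lowest in RPMI8226 were EYA2, a developmental transcription cofactor gene, at 4.26 against 9.69 in KMS11 and 10.0 in U266, and LAPTM4B, CCDC88A, CLGN, RALGPS2 and SYT11. In KMS11, RORB, MAP1B, FGFR3, ZNF532, PLXDC2 and ZC3H12B were highest, with RORB at 8.55 against 3.08 in RPMI8226 and 3.03 in U266. ZNF100, GTSF1, EGR1, CD53, ZNF431 and LIN28B were lowest there. EGR1, an immediate early gene, averaged 3.81 in KMS11 against 8.54 and 8.92.

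In U266, the leukocyte receptor genes CD180 and SLAMF6 averaged 10.1 and 9.27 log2 units, against 2.71 and 2.56 in KMS11, and lay 7.05 and 6.76 log2 units above RPMI8226. CCL3L1, CCR2, EDNRB and DCC were also highest there. CCL3L1 has near-identical copies, so its probe set is uncertain. CERS6, DSG2, IQGAP2, CLIC2, ADCY1 and APP were lowest in U266, with APP, the amyloid precursor protein gene, at 4.64 against 9.59 and 9.66. Each of these genes passed both pairwise contrasts of its line. Levels near 2 to 3 log2 units lie at the low end of the arrays, so the sizes against them are uncertain.

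Most members of the fixed lists differed between lines, as did 82.4% of all tested genes, so a high count alone does not set a list apart. Some lists lay below that share, among them the IGF axis (4 of 7), microRNA machinery (5 of 8) and hypoxia genes (11 of 15). The examples given here were picked after their values were seen. All 11 tested p53 targets differed, 7 of them highest in RPMI8226, 4 in KMS11 and 0 in U266. PMAIP1, encoding NOXA, stood at 8.74, 8.92 and 4.67 in RPMI8226, KMS11 and U266. Of 37 cell cycle genes, 35 differed and 20 were highest in KMS11, with CCNE1, encoding cyclin E1, at 5.75, 8.02 and 7.12. Of 18 interferon-stimulated genes, 16 differed and 12 were highest in U266, with USP18 at 5.17, 5.96 and 8.45 and IFIT3 at 2.97, 4.96 and 6.96. All 16 cholesterol synthesis genes differed and 9 were highest in U266. All 8 TGF-beta genes differed and 7 were highest in KMS11. Of 11 plasma cell genes, 10 differed, with CD38 at 9.95 in RPMI8226 and 3.96 in U266, and SDC1 at 7.23, 5.62 and 9.49. Of the 25 miR-10 family targets, 24 differed, with TIAM1, a Rac exchange factor gene, at 3.93, 4.92 and 8.21. The fit cannot say how these line differences bear on the response to the mimic.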

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

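The test of 1 line's mimic effect against that of the other 2, and the rules that drew attention to the values given here, were applied after the per-line values were seen. The IGF axis, insulin-like growth factor ligands, receptors, binding proteins and adaptors, stood out because its median change had opposite signs in 2 lines, -0.17 log2 units in RPMI8226 and 0.16 in KMS11, both outside the central 95% of random lists matched on expression. In RPMI8226, 5 of its 7 tested members were lower with mimic, and in KMS11 1 was. IGFBP3, a binding protein gene, gave -0.17, 0.41 and 0.36 in RPMI8226, KMS11 and U266, and IGFBP4 gave -0.18, 0.15 and 0.69. Against the other 2 lines the list did not pass for RPMI8226 (camera adjusted p = 0.0963 over 54 combinations of list and line) or for KMS11 (0.594). Interferon-stimulated genes differed in U266 from the mean of the other lines by a median of -0.28, called by camera with the preset correlation (adjusted p = 4.37e-05) but not with the correlation of 0.15 estimated in that fit given as a value (adjusted p = 0.249). Over the 54 combinations of list and line, 5 medians lay outside the central 95%, where chance gives 2.7. Besides the 2 IGF axis medians and that of interferon-stimulated genes in U266, they were the cell cycle list in RPMI8226 (percentile 99.86) and ribosomal protein genes in KMS11 (99.07).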

How the results depend on the processing

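The values on all probe sets, on protein-coding genes only, of the line differences without an array, of the U266 interferon-stimulated genes under other scalings, of 1 line against the other 2 and of camera with a given correlation were chosen only after the data were seen. The count of 0 genes past limma's threshold was the same in every alternative run. Without the replicate block 0 genes and 0 lists were called, so the pairing changed no call. Genes at least 1.5-fold different in the same direction in all lines numbered 1 with no filter (LRRC27, named after its values were seen), 16 at 1.2-fold, and 2 to 3 without a line. Lists called numbered 0 to 2 without a line, and 0 with the estimated correlation given as a value (smallest adjusted p 0.0792). Fry called 0 lists over all lines (smallest adjusted p 0.139). In simulations it called a list shifted by 0.1 in 10%, so its 0 calls decide little. Camera with an estimated correlation called no list in simulations with shifted lists, so its 0 calls decide nothing. With no filter, list medians shrank to 0.0050 for HOX genes, 0.0402 for the IGF axis and 0.0192 for apoptosis regulators. In the upper 25% of genes by expression the median of myeloma oncogenes was 0.0019. As the mean of its probe sets, VIM gave 0.0797. List medians that turned sign were those of the NF-kB pathway (-0.0047), hypoxia genes (-0.0026) and plasma cell genes (-0.0081) with array medians centred, plasma cell genes (-0.0027) and microRNA machinery (0.0172) after quantile normalization, apoptosis regulators (-0.0070) in the upper 25% of genes by expression, and T cell and myeloid genes (-0.0010) with no filter. Without a line, list medians ranged from 0.0198 to 0.0994 for the IGF axis, -0.0218 to 0.0031 for the NF-kB pathway, -0.0211 to 0.0248 for plasma cell genes, -0.261 to 0.120 for B cell genes, -0.135 to 0.0043 for interferon-stimulated genes, -0.00066 to 0.0047 for hypoxia genes, -0.0134 to 0.0261 for cholesterol synthesis, -0.0066 to 0.0625 for myeloma oncogenes, -0.0475 to 0.0422 for microRNA machinery, -0.0659 to -0.0297 for miR-10 family targets, 0.0066 to 0.0454 for the cell cycle, 0.0283 to 0.0989 for p53 targets, 0.0133 to 0.128 for HOX genes, -0.0463 to -0.0040 for the TGF-beta pathway and 0.0234 to 0.0418 for apoptosis regulators. Gene changes ranged from -0.0530 to 0.280 for HOXB9, -0.0141 to 0.423 for IGFBP4, -0.106 to 0.266 for KIF20A, -0.0049 to 0.0430 for VIM, -0.0656 to 0.377 for CD8A, -0.284 to 0.0158 for MYC and -0.0310 to 0.192 for MAF. The cause of these turns was not tested. The U266 median of interferon-stimulated genes was -0.22 after quantile normalization and -0.26 with medians centred. The test of 1 line against the other 2 called 0 genes for each line (smallest adjusted p 0.254). Line differences numbered 5729 to 5978 genes without an array, 6153 after quantile normalization and 7561 of 14884 with no filter. The test of miR-10a seed sites and its alternatives were not run, and a pseudocount did not apply to log2 values. Signal over background is unknown, which limits every weakly expressed gene.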

Other observations

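The tests of the interferon-stimulated genes against random lists and against the spread of U266, the test of U266 against the other 2 lines with either correlation, and both tests of the microRNA probe sets were chosen only after the result was seen.

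A second list of 50 interferon-induced genes, none of them on the fixed list, had 21 tested members. In U266 20 of these were lower with mimic, with a median of -0.19 log2 units, or -0.15 after quantile normalization. Its lowest members there, picked after their values were seen, were IFITM1, an antiviral membrane protein gene, at -0.61 and SP110, a nuclear body gene, at -0.50. TRIM14 followed at -0.48 and LAP3, an aminopeptidase gene, at -0.43. The second list's median was -0.05 in RPMI8226, with 15 members lower, and 0.05 in KMS11, with 6 lower.

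The lower interferon-stimulated genes in the U266 pair are weighed first. Of 10000 matched random lists, 0 had a median as low. That value had been seen when the test was chosen, so it is no independent evidence against noise of unrelated genes at this level. A change of the fixed list's members alone is argued against by 0 of 10000 for the second list, in the same pair of arrays. A wider spread of the pair is argued against by an SD ratio of 1.013 to the wider other line. Random lists lack the co-variation of these genes, and camera's adjusted p for U266 against the other 2 lines was 4.37e-05 with the preset correlation and 0.249 with a correlation of 0.15, estimated from the difference between the changes of RPMI8226 and KMS11 alone, so co-variation stays open. The mimic may have lowered these genes, the scrambled control may have raised them, or the cultures may have differed in handling, and 1 array each leaves all of these open. The median level of the fixed list was 7.37 in the U266 control and 6.87 with mimic, against 5.53 and 6.05 in the controls of RPMI8226 and KMS11.

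A hypothesis is that the mimic slightly lowers miR-10 family targets. The list's median lay at percentile 1.11 of matched random lists and at 1.39 without RORA, its lowest member, which decides nothing because a median of 25 hardly moves with 1 member, and camera's p was 0.0097 with RORA and 0.0324 without it. The list's adjusted p was 0.23 to 0.25 without a line, 0.418 with no filter and 0.522 without the block. Of the 10 splits of the 6 arrays, 1, the real one, gave a list p as small (0.0599 being the lowest of the others), and the counts of called genes (highest other 0) and called lists (highest other 2) decide nothing, since all 10 splits must reach the real counts of 0. Only 4 splits part all 3 pairs as the real one does, the other 3 with a list p of 0.178 to 0.594, while 6 part only 1 pair and rest on it alone, so for the list p the splits are too few for a share under 0.05. The p53 targets, 10 of 11 of them higher, reached the same adjusted p (limma's camera, 0.088). That p therefore does not single out miR-10 family targets.

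MicroRNA genes made up 7 of the 24 genes named by rule, 5 lower and 2 higher, against 2.67% of tested genes. A wider spread of these probe sets between arrays is a candidate explanation: their median absolute change was at least 1.588 times that of protein-coding genes at the same level in every line. Across the 199 microRNA genes, a correlation of -0.0989 between RPMI8226 and U266 argues against a response of the class shared by all 3 lines. The 7 named ones were picked for the same direction in all 3 lines, so a shared response of these alone stays open. The other correlations were 0.207 between RPMI8226 and KMS11 and 0.0745 between KMS11 and U266, so a response shared by RPMI8226 and KMS11 stays open. Whether these probe sets detect the precursor or other sequence was not tested.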
